A study of Homo sapiens with 6 samples.

How the data were processed

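RL cells with the t(14;18) translocation were profiled on Affymetrix Gene 1.0 ST arrays, 3 untreated and 3 given LY317615, with 48 h in every sample title. RNA was extracted with TRIzol and cleaned on RNeasy columns, and 100 ng of it was turned into biotin-labelled single-stranded DNA, per the labels. The deposited values are intensities on a linear scale, per probe set and array, for 33297 probe sets. Per the submitters' processing notes RMA, Affymetrix Expression Console and GCOS 1.4 were used; their order, and the versions of the first 2, are not given in the sources used here. RMA gives log2 values, so the linear scale implies a step back from log2 that is not stated. Log2 was taken of the deposited values with no added constant, since all were above 0, and no further scaling was applied.

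Of the probe sets, 19460 were annotated to exactly 1 gene symbol, 1754 to several and 12083 to none. Only the first kind was tested as genes. For the 769 genes with several such probe sets, the probe set with the highest mean over the 6 arrays was used, which left 18417 genes. No detection calls were used, so it is not known which dim genes were above background, and no filter on intensity was applied. The arrays came with no scan dates or batches in the sources used here, and no genome build was named, so no coordinates are given.

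The samples were grouped by their labels. Each gene was tested with a linear model and moderated t (limma 3.58.1 in R 4.3.3, eBayes without trend), all tests being two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors of fold changes are standard errors from that model, and errors of group means are SDs over 3 arrays. Principal components and Pearson correlations described the arrays. Other tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

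The gene lists, the rule for naming genes, the tests and the alternatives below were fixed before the data were examined, except where said otherwise. Of the fixed lists, 36 had at least 5 measured genes and were tested with camera at its preset correlation of 0.01, adjusted over the lists. Beside it stand camera with the correlation estimated from the residuals, camera on ranks, fry, and counts of members past the threshold over all genes and adjusted over the list alone. Camera tests a list against the other genes, while fry tests it against no change, so their p-values answer different questions. The estimated correlation rests on few residual degrees of freedom. Older gene symbols in the lists were brought to current ones. A further 7 lists were added after the data were seen and were adjusted among themselves; since their strongest members may have prompted them, each was also tested without its 3 members of smallest adjusted p.

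Genes were named by rule: the 12 largest rises and 12 largest falls among genes that passed and whose groups did not overlap; up to 4 members of each list that passed, by smallest adjusted p, or the 2 with the largest change where none passed; and always PRKCB, PRKCA, AKT1, GSK3B and BCL2. This gave 156 genes. ISG20, MCL1, BCL2L1, BAD and the members of the added lists other than NR1D2, SLAMF7 and SLAMF1 fall outside it. So do PHLDA1, NR4A2, CCND1, IER3, the DUSP and SPRY genes, SESN3, PIK3IP1, SESN1, IRS2, CAD and SRM.

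The code was tested on simulated data with 200 changed genes at the spread of these arrays. It made 193 calls, of which 7 were false, and recovered 79.1% of changes of 0.5 on the log2 scale and 100% of changes of 1 and 2. A list shifted by 0.5 was called, and 0 of the other lists were. Simulated genes varied independently of each other, and in the real data 6568 genes were called. These results therefore check the code, and not its error rates or recovery on the real arrays.

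The alternatives were the replicate number as a block, leaving out each array in turn, a variance prior with an intensity trend or robust to outlying genes, array weights, array medians set equal, cyclic loess, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, all probe sets, an adjusted p of 0.01 and a log2 fold change of at least 1. A comparison of each list's median with 10000 random lists matched in 20 bins of intensity was added after the data were seen. Probe sets without a gene name and those of several genes were left out of the gene tests and fitted on their own.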

Results

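RL is an established human B-cell lymphoma line that carries the t(14;18) translocation, which places BCL2 next to the immunoglobulin heavy-chain locus. LY317615, also known as enzastaurin, is a kinase inhibitor developed against protein kinase C beta. Total RNA of RL cells was profiled on Affymetrix Gene 1.0 ST arrays, which measure each transcript with a set of probes (a probe set). There were 3 untreated arrays and 3 arrays of cells given LY317615, all at 48 h. The labels give the dose as 2.5 mM, and this unit could not be checked here. They name no vehicle for the untreated cells. The comparison asks which transcripts differed between treated and untreated cells.

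Of 33297 probe sets, 19460 had a single gene name, and they stood for 18417 genes. Median probe-set intensity ran from 56.7 to 58.2 over the untreated arrays and from 60.0 to 61.4 over the treated arrays. The number of arrays limits the precision. The series text calls the replicates independent, but the labels do not say that they came from separate cultures, so p-values measure only the spread between these arrays, which may be partly technical. Across genes, which are not independent replicates, log2 intensities correlated at 0.997 within the untreated group and at 0.994 to 0.997 within the treated group. Between the groups the correlation was 0.982 to 0.989. The first principal component held 71.4% of the variance and parted the untreated from the treated arrays. Slopes of the treated arrays on the mean of the untreated arrays were 0.955, 0.951 and 0.919, against 0.994 to 1.005 for each untreated array on the others. Treated replicate 3 stood apart from the other treated arrays: it lay at 15.8 on the second principal component, against -6.29 and -13.7, and had an array weight of 0.376, against 1.04 to 1.51 for the other 5 arrays.

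After 48 h with LY317615, RL cells had less RNA for ribosome assembly, for cholesterol and fatty acid synthesis and for germinal-centre B-cell markers. RNA of interferon-response genes was higher. These 5 groups passed in camera with its preset correlation, and 0 of 36 lists passed with an estimated correlation (smallest adjusted p = 0.303). MYC, the driver of ribosome and growth genes, fell 2.49-fold, and BCL6, a transcriptional repressor and germinal-centre marker, fell 2.34-fold. MME, which encodes the surface marker CD10, rose 4.47-fold, and the interferon-induced IFI6 rose 3.83-fold. In all, 6568 of 18417 genes (35.7%) passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 2622 higher and 3946 lower.

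Most of these changes were small. The median size was 0.41 on the log2 scale, and 4399 genes changed by less than 0.5. Changes of at least 1 were seen in 55 genes that rose and 189 that fell. The groups did not overlap in 6503 of the genes that passed. Over all genes they did not overlap in 49.8%, against 10% by chance for 3 arrays against 3. Lower genes made up 60.1% of the changed genes. That share was 71.4% (1810 higher, 4526 lower) with the array medians set equal, and 53.5% (2588 higher, 2979 lower) after cyclic loess, which removes trends with intensity.

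Changes varied with intensity. Over 5 equal bins of named genes from dim to bright, the median log2 fold change was 0.06, 0.15, 0.11, -0.14 and -0.21. In the dimmest bin 248 genes rose and 87 fell, and in the brightest 349 rose and 1755 fell. Probe sets without a gene name, given the same limits of intensity, had medians of -0.02, 0.08, 0.04, 0.06 and 0.06.

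**Figure D1:**
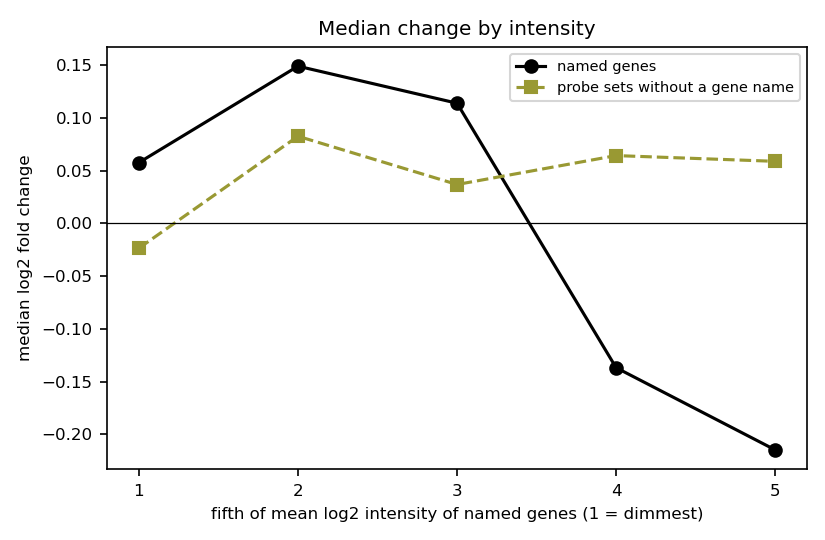
Median log2 fold change (LY317615 minus untreated, y axis) in each of 5 equal bins of mean log2 intensity (x axis, 1 the dimmest) for named genes and for probe sets without a gene name. Named genes go from 0.06 in the dimmest to -0.21 in the brightest bin, while probe sets without a gene name go from -0.02 to 0.06.

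**Figure D2:**
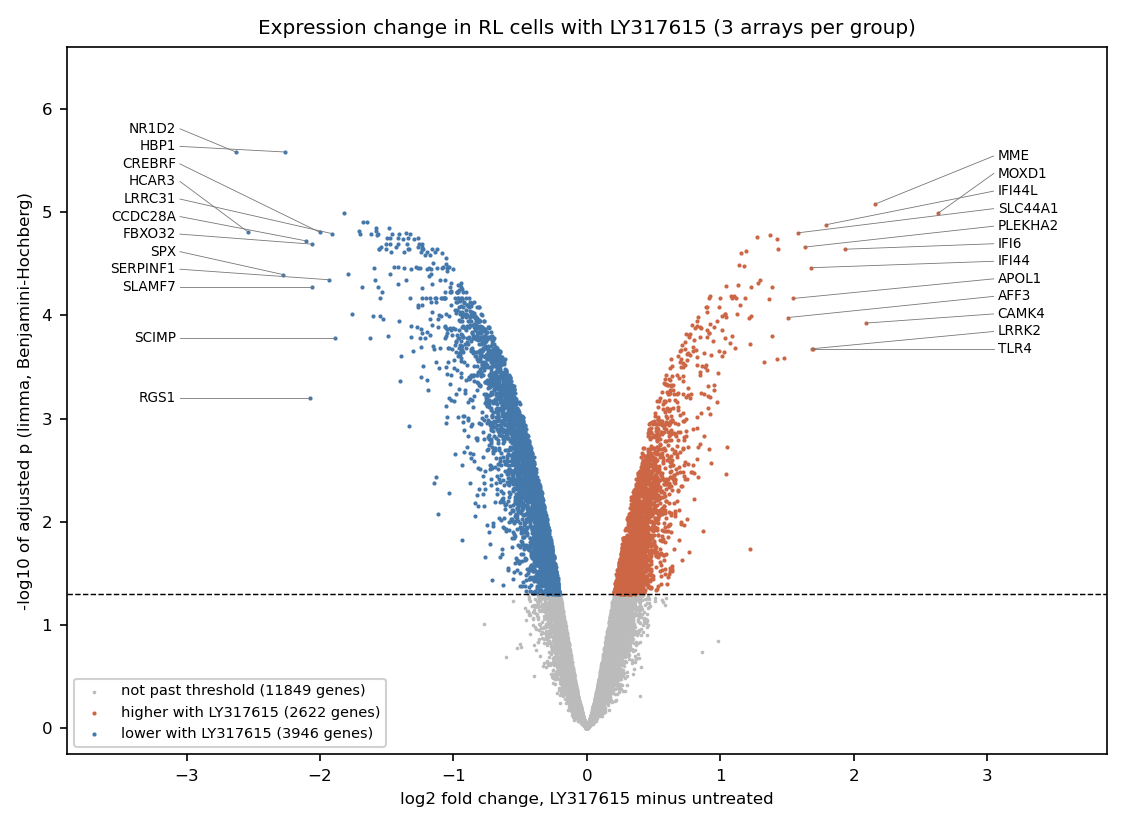
Log2 fold change (LY317615 minus untreated, x axis) against -log10 of the limma adjusted p (y axis) for 18417 genes, with 3 arrays per group. Points above the dashed line are the 2622 genes that rose and the 3946 that fell, and the 12 largest changes in each direction are named.

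The largest rise was that of MOXD1, a monooxygenase-like gene (probe set 8129573), at a log2 fold change of 2.63 ± 0.12 (SE, adjusted p = 1.03e-05). Its log2 intensity went from 4.70 ± 0.13 to 7.34 ± 0.21 (SD, n = 3). MME (probe set 8083494) rose from 9.56 ± 0.11 to 11.72 ± 0.09 (SD, n = 3), a change of 2.16 ± 0.09 (SE). CAMK4, a calcium and calmodulin-dependent kinase, rose by 2.09 ± 0.19. The interferon-induced IFI6, IFI44L and IFI44 rose by 1.94 ± 0.12, 1.79 ± 0.09 and 1.68 ± 0.12. TLR4, the receptor for lipopolysaccharide, rose by 1.69 ± 0.18 and the kinase gene LRRK2 by 1.69 ± 0.18. PLEKHA2, the choline transporter SLC44A1, APOL1 and the transcriptional regulator AFF3 rose by 1.51 to 1.63. MOXD1, CAMK4, TLR4 and LRRK2 were dim before treatment, between the 17.6th and 23.6th percentile of untreated log2 intensity.

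NR1D2 (probe set 8078272), which encodes the nuclear receptor REV-ERB beta of the circadian clock, had the largest fall. Its log2 intensity went from 8.29 ± 0.10 to 5.66 ± 0.11 (SD, n = 3), a change of -2.63 ± 0.09 (SE, adjusted p = 2.61e-06). HBP1, a transcriptional repressor linked to cell-cycle arrest, went from 10.19 ± 0.06 to 7.93 ± 0.07 (SD, n = 3), a change of -2.26 ± 0.08 (SE). HCAR3 changed by -2.54 ± 0.13, but its near-identical neighbour HCAR2 may share its probes, so the value may hold both. SPX, CCDC28A and FBXO32, a ubiquitin ligase gene induced by FOXO factors, changed by -2.28 ± 0.16, -2.10 ± 0.12 and -2.06 ± 0.12. Among genes of lymphocyte signalling, RGS1 changed by -2.07 ± 0.27, SLAMF7 by -2.06 ± 0.16 and the adaptor gene SCIMP by -1.89 ± 0.19. CREBRF, SERPINF1 and LRRC31 changed by -2.00 ± 0.10, -1.93 ± 0.14 and -1.91 ± 0.10.

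**Figure D3:**
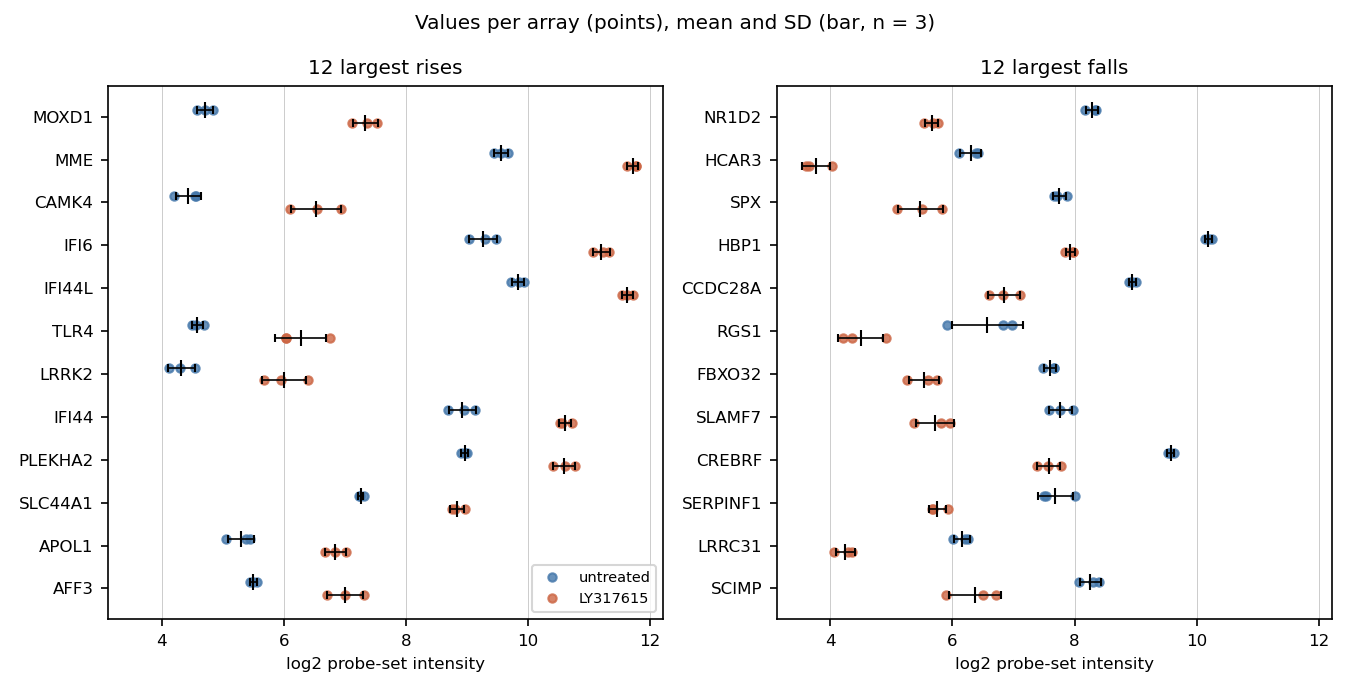
Log2 probe-set intensity on each of the 6 arrays (points) for the 12 largest rises (left) and the 12 largest falls (right), with mean and SD (n = 3) as bars. Genes were eligible only if their groups did not overlap; MOXD1 goes from 4.70 to 7.34 and NR1D2 from 8.29 to 5.66.

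Genes of ribosome assembly and MYC targets, tested as 1 list, fell together. The list also holds MYC targets that are not assembly factors, such as CAD and SRM. Of 29 measured genes, 26 fell and 0 rose, with the same counts adjusted over the list alone. NOP16 changed by -0.96 ± 0.07 (SE), DDX10 by -0.96 ± 0.08, NOLC1 by -0.87 ± 0.07 and WDR43 by -0.77 ± 0.07. The median was -0.69, and camera with its preset correlation gave an adjusted p of 2.70e-13 (adjusted p = 0.303 with an estimated correlation). The protein components of the cytosolic ribosome went the other way: of 25 measured genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone). RPS9 rose by 0.47 ± 0.07, RPL7 by 0.48 ± 0.08, RPL10A by 0.40 ± 0.07 and RPS2 by 0.35 ± 0.07. Their median was 0.21 (adjusted p = 0.000223; adjusted p = 0.533 with an estimated correlation), and 0.41 after cyclic loess. Many ribosomal protein genes have processed pseudogenes that can share probes with them.

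Some growth-signal and cell-cycle genes fell. Among 30 measured immediate-early genes and targets of the ERK kinases, 14 fell and 4 rose (16 and 6 adjusted over the list alone). MYC went from 11.62 ± 0.08 to 10.31 ± 0.14 (SD, n = 3), a change of -1.32 ± 0.09 (SE). The activation marker CD69 changed by -1.41 ± 0.13 and the ERK-dependent factors ETV5 and ETV4 by -1.24 ± 0.10 and -0.74 ± 0.08. The 4 genes that rose, named after their values were seen, were PHLDA1 (0.44), NR4A2 (0.35), CCND1 (0.34) and IER3 (0.29). Of the DUSP and SPRY genes, also named afterwards, DUSP2 changed by -0.68, while DUSP4, DUSP5, DUSP6, SPRY1, SPRY2 and SPRY4 were not called. The list had an adjusted p of 0.0399 (adjusted p = 0.533 with an estimated correlation), which became 0.126 on ranks, 0.0736 without the dimmest 30% of genes, 0.0641 without untreated replicate 3 and 0.054 without treated replicate 1.

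Of 36 measured genes of the G1/S transition and DNA replication, 15 fell and 2 rose, with the same counts adjusted over the list alone. The replicative helicase genes MCM6, MCM5 and MCM2 changed by -0.98 ± 0.08, -1.04 ± 0.11 and -0.82 ± 0.10 (SE), and the DNA glycosylase gene UNG by -0.95 ± 0.10. Of 33 G2/M and mitotic genes, 17 fell and 0 rose, again with the same counts adjusted over the list alone. The kinase genes TTK and PLK1 changed by -0.89 ± 0.10 and -0.72 ± 0.12, CENPF by -0.86 ± 0.12 and KIF2C by -0.71 ± 0.12. The median was -0.28 in both lists. G1/S genes had an adjusted p of 0.00217 (adjusted p = 0.623 with an estimated correlation), which became 0.278 after cyclic loess. For G2/M genes it was 0.000223 (adjusted p = 0.567 with an estimated correlation), and 0.136 after cyclic loess. Tested with fry against no change, neither list passed (adjusted p = 0.0794 for G1/S and 0.0537 for G2/M). Median changes after cyclic loess were -0.08 in both lists. Treated replicate 3 had the lowest values of all 8 named genes of these lists; without it the G1/S median was -0.15 (adjusted p = 0.0446) and the G2/M median -0.21 (adjusted p = 0.0033).

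The lists of histones and of cell-cycle inhibitors did not pass. Of 28 replication-dependent histone genes, 14 rose and 6 fell (14 and 8 adjusted over the list alone; adjusted p = 0.0969). H3C11 rose by 0.75 ± 0.08 (SE), while H3C10, H2BC21 and H2AC17 changed by -1.21 ± 0.12, -1.02 ± 0.13 and -0.67 ± 0.08. Histone genes are close copies of each other, so probes may be shared. The histone list passed without treated replicate 3 (adjusted p = 0.0176), with an intensity trend in the variance prior (0.0307), with array weights (0.0369) and after cyclic loess (0.0159). Among 19 CDK inhibitors and cell-cycle exit genes, 7 fell and 1 rose (7 and 2 adjusted over the list alone; adjusted p = 0.298). RBL2, a pocket protein that restrains E2F, changed by -0.55 ± 0.07, TOB1 by -0.62 ± 0.08, MXI1 by -0.53 ± 0.08 and GADD45B by -0.48 ± 0.08.

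Most measured lipid synthesis genes fell. Of 19 genes of cholesterol biosynthesis and its control, 17 fell and 0 rose (17 and 1 adjusted over the list alone). INSIG1, a sterol sensor gene that is itself a target of SREBP factors, went from 10.81 ± 0.14 to 9.30 ± 0.05 (SD, n = 3), a change of -1.50 ± 0.09 (SE). HMGCS1 and DHCR7, enzymes early and late in the pathway, changed by -1.06 ± 0.10 and -0.94 ± 0.08, and SREBF2, which encodes its main activator, by -0.97 ± 0.07. Fatty acid synthesis showed 7 of 13 genes lower and 0 higher, with the same counts adjusted over the list alone. The desaturase gene SCD changed by -1.20 ± 0.08, FASN by -0.81 ± 0.07, ACACA by -0.54 ± 0.07 and SREBF1 by -0.51 ± 0.07.

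The cholesterol list had a median of -0.45 and an adjusted p of 3.57e-07 (adjusted p = 0.527 with an estimated correlation). The fatty acid list had a median of -0.34 and an adjusted p of 0.00299 (adjusted p = 0.303 with an estimated correlation). After cyclic loess these medians were -0.30 and -0.12. Of 9 LXR targets and cholesterol efflux genes, 3 fell and 0 rose, with the same counts adjusted over the list alone: SREBF1, SMPDL3A at -0.66 ± 0.11 (SE) and the cholesterol exporter gene ABCA1 at -0.46 ± 0.08. That list did not pass in camera (adjusted p = 0.0848), but did without treated replicate 3 (0.0498). In fry, which tests a list against no change and not against other genes, it passed (adjusted p = 0.00299).

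Most germinal-centre B-cell markers fell. Of 23 measured genes, 17 fell and 1, MME, rose (18 and 2 adjusted over the list alone). BCL6 went from 11.98 ± 0.06 to 10.75 ± 0.08 (SD, n = 3), a change of -1.23 ± 0.08 (SE). IRAG2 changed by -1.34 ± 0.08, the inositol kinase gene ITPKB by -1.26 ± 0.08 and BACH2, a repressor of plasma-cell fate, by -1.23 ± 0.07. The list had a median of -0.48 and an adjusted p of 5.42e-07 (adjusted p = 0.303 with an estimated correlation), with a median of -0.25 after cyclic loess.

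Markers of other B-cell stages did not pass as lists. Of 18 naive and memory markers, 7 fell and 3 rose, with the same counts adjusted over the list alone (adjusted p = 0.298). FCER2, the low-affinity IgE receptor gene CD23, changed by -1.55 ± 0.10 (SE), IL4R by -1.02 ± 0.08, CCR7 by -1.03 ± 0.14 and CD27 by -0.48 ± 0.07. Among 17 plasma-cell genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.298). SLAMF7, TNFRSF17, which encodes the receptor BCMA, and FKBP11 were among those that fell, TNFRSF17 by -1.49 ± 0.15 and FKBP11 by -0.78 ± 0.09. The median of the plasma-cell list was 0.05, its mean was -0.27 and the test pointed down; the median was -0.001 with the array medians set equal and after cyclic loess.

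B-cell receptor signalling genes moved both ways. Of 27 measured genes, 8 fell and 3 rose (10 and 4 adjusted over the list alone; adjusted p = 0.211). The guanine exchange factor gene VAV3 changed by -1.54 ± 0.09 (SE) and the inhibitory receptor gene CD22 by -1.16 ± 0.10. The kinase gene LYN rose by 0.62 ± 0.09 and the inhibitory Fc receptor gene FCGR2B by 0.43 ± 0.08. Of 26 chemokine receptors, homing receptors and adhesion genes, 10 fell and 4 rose (11 and 5 adjusted over the list alone; adjusted p = 0.429). CXCR4 changed by -1.06 ± 0.09, ICAM2 by -0.71 ± 0.08 and RGS2 by -0.94 ± 0.11. PECAM1 rose by 1.12 ± 0.09 on its brighter probe set, while a further probe set of it read -0.03 (adjusted p = 0.921).

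The kinase that the compound was developed against was dim on these arrays. PRKCB (probe set 7994131) had a log2 intensity of 4.99 ± 0.05 in untreated and 4.99 ± 0.09 in treated cells (SD, n = 3), at the 28.6th percentile of untreated intensity. Its log2 fold change was -0.001 ± 0.078 (SE, adjusted p = 0.992). Of 11 measured protein kinase C and D genes, 4 fell and 1 rose (5 and 2 adjusted over the list alone; adjusted p = 0.256). PRKCH changed by -1.12 ± 0.10, PRKCA by -0.73 ± 0.11, PRKCD by -0.66 ± 0.09 and PRKCE by -0.44 ± 0.08. GSK3B, a kinase gene downstream of AKT, rose by 0.52 ± 0.07 (adjusted p = 0.000679). AKT1 rose by 0.28 ± 0.09 (adjusted p = 0.041), a call that was lost with the array medians set equal, with the replicate number as a block, without untreated replicate 2 or 3, and without treated replicate 1 or 2. BCL2, the gene of the translocation, rose by 0.30 ± 0.08 (adjusted p = 0.0168), a call that was lost without untreated replicate 1 or 2 and without treated replicate 1.

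Interferon-response genes rose as a group. Of 30 measured genes, 22 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 0.81. IFI44L went from 9.84 ± 0.10 to 11.63 ± 0.08 and BST2, a gene that tethers budding viruses, from 8.83 ± 0.05 to 10.11 ± 0.03 (SD, n = 3). The change of BST2 was 1.28 ± 0.07 (SE). The exception was ISG20, an exonuclease gene named after its value was seen, at -0.34 ± 0.09, a call lost after cyclic loess. The list had an adjusted p of 2.14e-10 (adjusted p = 0.533 with an estimated correlation).

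Antigen presentation genes rose in part, and NF-kB targets went both ways. Of 10 measured MHC class I genes, 4 rose and 0 fell, with the same counts adjusted over the list alone. These were B2M, the light chain of class I molecules, at 0.79 ± 0.07 (SE), the peptide transporter genes TAP1 and TAP2 at 0.72 ± 0.10 and 0.34 ± 0.08, and the immunoproteasome gene PSMB9 at 0.61 ± 0.08. The class I heavy-chain genes were not analysed here, and the list's adjusted p of 0.0372 (adjusted p = 0.533 with an estimated correlation) was lost under several settings. It became 0.0717 on ranks, 0.051 with the replicate number as a block, 0.0502 without untreated replicate 3, 0.0825 without treated replicate 1 and 0.0688 without treated replicate 2, and its median of 0.13 became 0.34 after cyclic loess and 0.07 with the array medians set equal. Of 13 MHC class II genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.249, and 0.00623 after cyclic loess). HLA-DMB rose by 0.68 ± 0.08, HLA-DQB1 by 0.71 ± 0.14, HLA-DQA1 by 0.41 ± 0.08 and HLA-DPB1 by 0.31 ± 0.08; these genes are polymorphic and their probes may read other alleles differently. Of 31 NF-kB targets, 11 fell and 7 rose (12 and 8 adjusted over the list alone; adjusted p = 0.587). SLAMF1 changed by -1.60 ± 0.14, PLEK by -1.18 ± 0.09 and CCR7, also a naive-cell marker, was among those that fell, while TNFAIP2 rose by 0.55 ± 0.07.

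Stress-response genes were mostly lower. Of 28 targets of ATF4 and the integrated stress response, 17 fell and 1 rose (19 and 1 adjusted over the list alone). The glutathione-degrading enzyme gene CHAC1 changed by -0.79 ± 0.08 (SE), WARS1 by -0.82 ± 0.08 and VLDLR by -0.87 ± 0.09. The cystine transporter gene SLC7A11 rose by 0.91 ± 0.07. The list had a median of -0.40 and an adjusted p of 6.73e-05 (adjusted p = 0.527 with an estimated correlation), with a median of -0.25 after cyclic loess. Of 15 heat shock proteins and co-chaperones, 8 fell and 0 rose (10 and 0 adjusted over the list alone), among them HSPH1 at -0.56 ± 0.08, HSPA4 at -0.44 ± 0.07, DNAJB4 at -0.40 ± 0.07 and HSP90AA1 at -0.33 ± 0.08. Their median was -0.27 (adjusted p = 0.00127; adjusted p = 0.527 with an estimated correlation), and -0.15 after cyclic loess.

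The unfolded protein response list had 13 of 28 genes lower and 0 higher (14 and 1 adjusted over the list alone). HERPUD1 changed by -0.99 ± 0.08 (SE), DNAJB9 by -0.75 ± 0.08, the chaperone gene HSPA5 by -0.57 ± 0.08 and HYOU1 by -0.43 ± 0.07. Among 28 proteasome subunits, 14 fell and 1 rose (14 and 2 adjusted over the list alone), including PSMB1 at -0.63 ± 0.07, PSMC4 at -0.59 ± 0.08, PSMD12 at -0.57 ± 0.07 and PSMD8 at -0.51 ± 0.08. The adjusted p was 0.0259 for the unfolded protein response (adjusted p = 0.533 with an estimated correlation) and 0.000715 for the proteasome (adjusted p = 0.533 with an estimated correlation). After cyclic loess these became 0.887 and 0.801, and the medians of -0.19 and -0.22 became -0.006 and 0.002, so the proteasome median changed sign. The unfolded protein response was also lost without treated replicate 3 (0.0644) and without the dimmest 30% of genes (0.112).

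Energy metabolism genes were lower in part. Of 28 genes of glycolysis and the hypoxia response, 13 fell and 1 rose (15 and 3 adjusted over the list alone). The mitophagy receptor gene BNIP3L changed by -1.25 ± 0.12 (SE), PDK1 by -1.01 ± 0.08, the hexokinase gene HK2 by -0.91 ± 0.09 and VEGFA by -0.64 ± 0.09. Of 28 genes of oxidative phosphorylation, 9 fell and 0 rose, with the same counts adjusted over the list alone. COX5B changed by -0.69 ± 0.08, NDUFA9 by -0.68 ± 0.08, SDHD by -0.66 ± 0.08 and NDUFS1 by -0.58 ± 0.07. The glycolysis list had a median of -0.24 and an adjusted p of 0.00404 (adjusted p = 0.533 with an estimated correlation), which became 0.161 after cyclic loess, with a median of -0.13, and 0.0503 without the dimmest 30% of genes. For oxidative phosphorylation the median was -0.13 and the adjusted p 0.0307 (adjusted p = 0.533 with an estimated correlation). After cyclic loess its median was 0.05 and its adjusted p 0.773. It was also lost without untreated replicate 2 (0.102) and without the dimmest 30% of genes (0.157).

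Autophagy, lysosome and FOXO target genes moved both ways and did not pass as lists. Of 27 autophagy and lysosome genes, 10 fell and 6 rose (10 and 7 adjusted over the list alone; adjusted p = 0.409). The autophagy genes MAP1LC3B and ATG14 changed by -0.88 ± 0.09 (SE) and -0.74 ± 0.08, while the lysosomal genes NPC2 and CTSA rose by 1.09 ± 0.11 and 0.70 ± 0.07. Of 25 FOXO targets, 11 fell and 4 rose, with the same counts adjusted over the list alone (adjusted p = 0.159). KLHL24 changed by -1.58 ± 0.08, TSC22D3, a glucocorticoid-induced gene, by -1.33 ± 0.07, and FBXO32 and BCL6 also fell. The 4 that rose, named after their values were seen, were SESN3 (1.23), PIK3IP1 (0.54), SESN1 (0.45) and IRS2 (0.38).

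Apoptosis genes also moved both ways. Of 17 BCL2 family genes, 6 fell and 4 rose, with the same counts adjusted over the list alone (adjusted p = 0.47). The pro-apoptotic genes BCL2L11, PMAIP1, BID and BMF changed by -0.84 ± 0.07 (SE), -0.55 ± 0.07, -0.40 ± 0.08 and -0.37 ± 0.08, and those of BID and BMF were not called after cyclic loess. The genes that rose were BCL2, MCL1, BCL2L1 and BAD, of which only BCL2 was fixed by the rule for naming, the others being named after their values were seen. MCL1 rose by 0.26 ± 0.07, BCL2L1 by 0.22 ± 0.08 and BAD by 0.32 ± 0.10. With the array medians set equal these were 0.21, 0.16 and 0.27 and were not called, and after cyclic loess they were 0.48, 0.38 and 0.34 and were called. Among 21 caspases and death receptors, 4 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.671). TRADD, CFLAR and FAS rose by 0.60 ± 0.10, 0.47 ± 0.09 and 0.34 ± 0.07 (a further CFLAR probe set read 0.24), and TNFRSF10B, a TRAIL receptor gene, changed by -0.66 ± 0.08. The median of that list was -0.02 and its mean 0.01, with the test pointing up; after cyclic loess the median was 0.01.

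Of 26 p53 targets, 9 fell and 6 rose (9 and 7 adjusted over the list alone; adjusted p = 0.559). The nuclease gene AEN changed by -0.98 ± 0.08 (SE) and TIGAR by -0.48 ± 0.07, beside TNFRSF10B and PMAIP1. Among 13 Wnt targets, 6 rose and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.627). BAMBI changed by -0.57 ± 0.08 and the transcription factor gene LEF1 by -0.47 ± 0.07, and NKD1 rose by 0.38 ± 0.09, a call lost after cyclic loess and without untreated replicate 3. The Wnt list had a median of 0.17 and a mean of -0.02, and its test pointed up while fry pointed down. Of 15 angiogenesis factors, 3 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.249). VEGFA fell, and PGF, MMP9 and FGF2 rose by 0.35 ± 0.10, 0.42 ± 0.13 and 0.46 ± 0.15. These 3 rises were each lost after cyclic loess and without untreated replicate 2, among other settings.

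Markers of other cell types were measured too. Of 13 T-cell markers, 4 rose and 0 fell, with the same counts adjusted over the list alone: CD7 by 0.58 ± 0.08 (SE), CD8A by 0.40 ± 0.08, CD3E by 0.45 ± 0.13 and CD28 by 0.35 ± 0.10. Of 15 myeloid markers, 6 rose and 0 fell (8 and 0 adjusted over the list alone), among them FCN1 by 0.56 ± 0.11, CD14 by 0.50 ± 0.10, MPO by 0.39 ± 0.13 and CD68 by 0.26 ± 0.08. Most of these genes were dim, with medians of log2 intensity of 5.04 for T-cell and 4.93 for myeloid markers. CD7 and TYROBP were not, at the 59.0th and 60.7th percentile of untreated intensity. The T-cell list had an adjusted p of 0.0186 (adjusted p = 0.533 with an estimated correlation), which became 0.227 after cyclic loess. The myeloid list had an adjusted p of 0.00217 (adjusted p = 0.527 with an estimated correlation), which became 0.0503 without the dimmest 30% of genes. Of 15 stromal and epithelial markers, 1 rose and 1 fell (0 and 1 adjusted over the list alone; adjusted p = 0.321): COL1A2 at 0.27 ± 0.09 and KRT18 at -0.48 ± 0.12. A further probe set of KRT18 went the other way, at 0.38 (limma adjusted p = 0.109), and KRT18 was not called when its probe sets were averaged. COL1A2 was not called in 9 of its alternative settings, among them both other scalings.

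**Figure D4:**
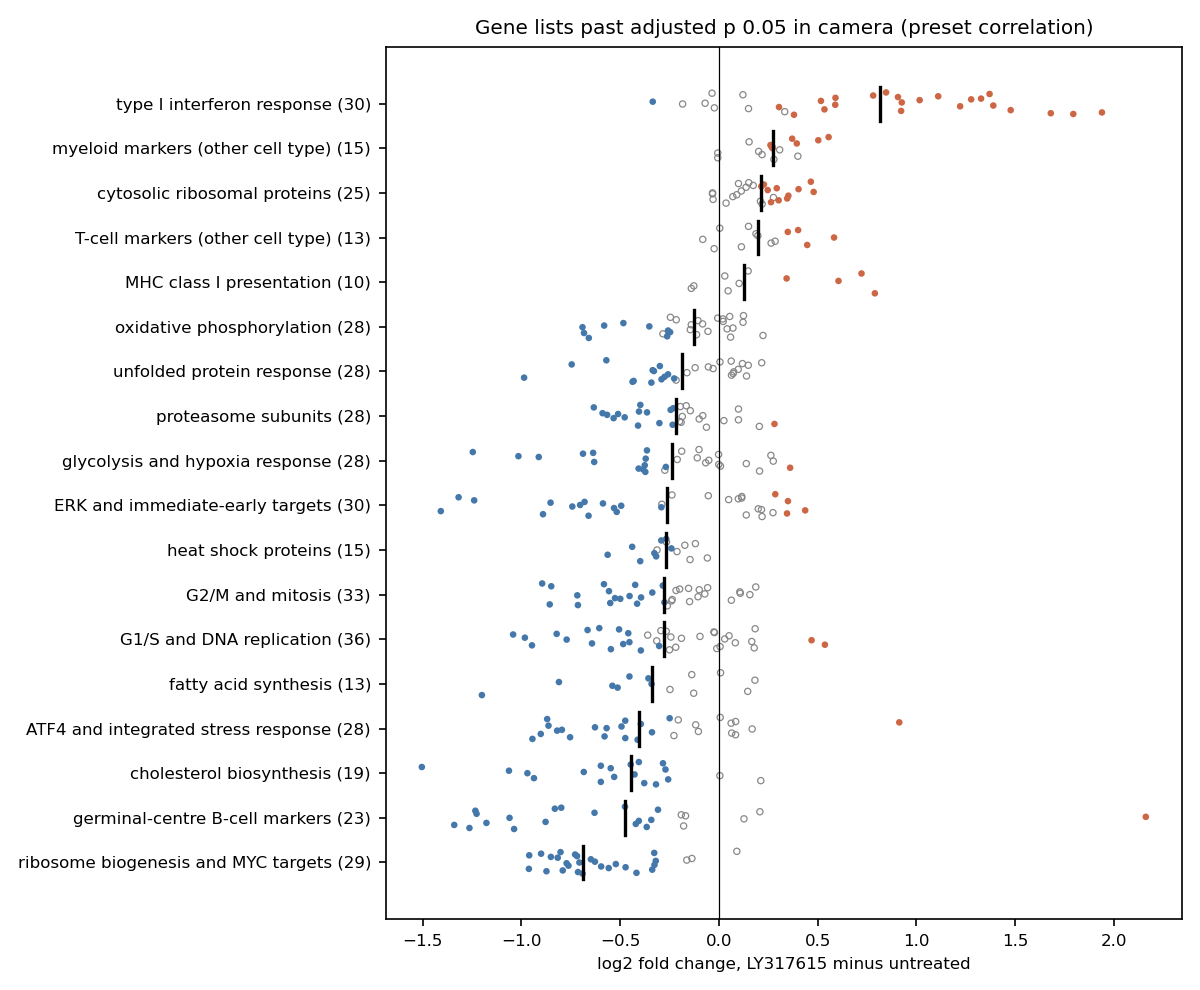
Log2 fold change (LY317615 minus untreated, x axis) of each measured member of the 18 lists past an adjusted p of 0.05 in camera with its preset correlation, with list size in brackets. Filled points passed the gene-level threshold (red higher, blue lower), open points did not and black bars are medians, from 0.81 for interferon-response genes to -0.69 for ribosome biogenesis; the oxidative phosphorylation and proteasome medians change sign after cyclic loess.

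Of 36 lists tested, 18 passed in camera with its preset correlation, 5 higher and 13 lower. With the correlation estimated from the residuals 0 passed, the smallest adjusted p was 0.303 and 3 had an unadjusted p under 0.05; fry, which asks whether a list changed at all, called 28, among them 12 that did not pass in camera with its preset correlation.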

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

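The tests of the T-cell and myeloid lists after cyclic loess, and that of bright genes that rose, were chosen only after the result was seen. Probe sets outside the gene tests also carried signal: fitted on their own, 1372 probe sets without a gene name passed the threshold (731 higher, 641 lower), as did 667 probe sets of several genes (363 higher, 304 lower). They drew attention because the gene-level comparison leaves them out. What they measure was not tested. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: the real split gave 6568 genes, as many as in 1 of the 10, and the highest other gave 0.

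Dim named genes tended to be higher and bright ones lower in treated arrays, by 0.272 between the median changes of the dimmest and brightest of 5 equal bins (95% interval 0.258 to 0.286). The intervals in this paragraph reflect the spread over genes and leave out that between arrays. A compression of whole arrays should act alike on probe sets without a gene name, but their difference was -0.0823 (95% interval -0.111 to -0.0565). These probe sets did not share the trend, but they cannot decide its cause. Where RMA evens out the arrays as a whole, a fall of bright named genes can by itself push other probe sets up. As the whole cause of the calls, compression is argued against by 349 genes of the brightest bin that rose, against 105 that the threshold allows as false in that bin. All 349 also rose after cyclic loess, but that scaling moves bright genes up in treated arrays, so this adds no support. How many of the other calls compression could account for stays open. After cyclic loess 65.7% of the called genes passed in the same direction, between the limits of 50% and 80% set beforehand. Treatment itself, the factor of the design, remains an open explanation of the trend that was not tested apart from the arrays.

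T-cell and myeloid marker lists were higher in treated arrays. RNA of other blood cells in the treated cultures stays open: 0 of 8 abundant transcripts (LYZ, S100A8, S100A9, TYROBP, CD14, CD3D, CD3E, CD2) both rose and stood above the median gene of the treated arrays, at 6.39, but only 1 of them, TYROBP, started within reach of that level, so the limit set beforehand could not exclude a small share of such cells. The trend with intensity may account for the T-cell list, whose median fell from 0.20 to 0.12 and whose adjusted p went from 0.0186 to 0.227 after cyclic loess. It does so less well for the myeloid list, which still passed (adjusted p = 0.0305). An effect of treatment on these genes, most of them dim, stays open.

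Interferon-response genes were higher in treated arrays, with a median of 0.81. No single treated array carried the rise, since the lowest median without a treated array was 0.751. The median was 0.891 after cyclic loess, but that scaling moves bright genes up in treated arrays, so this adds no support. For bright members the trend with intensity runs against the rise. The brightest bin had a median change of -0.21, while IFI44L and IFI6, at the 91.6th and 85.9th percentile of untreated intensity, rose. The rise may be an effect of treatment, as a hypothesis found and tested on the same arrays. No vehicle is named, so an effect of a vehicle cannot be told apart from it.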

How the results depend on the processing

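The comparison of lists with random lists was chosen after the data were seen. The count of 6568 genes stayed within 1.5 times under every alternative but the stricter thresholds: 244 genes (55 higher, 189 lower) with a log2 fold change of at least 1 and 3586 (967 higher, 2619 lower) at an adjusted p of 0.01, counts that are lower by construction. Leaving out 1 array gave 1566 to 2538 higher genes, with 1566 without untreated replicate 2 and 1715 without untreated replicate 3, where fewer arrays were tested. Same-numbered arrays of the 2 groups deviated together little (r = -0.017, 0.0932 and 0.0664 across genes, against -0.107 to 0.0438 for differently numbered ones). No label says whether the numbers pair the arrays, so pairing stays unknown. With a replicate block 6548 genes passed, and 6079 of the 6568 remained. Of the lists, 0 passed with an estimated correlation, 28 in fry and 11 lay outside the central 95% of random lists. Of 18 called lists, 8 kept their call and direction under every other setting fixed beforehand for lists, the estimated correlation aside. After cyclic loess the direction turned for oxidative phosphorylation (adjusted p = 0.773), B-cell receptor signalling (0.548), the BCL2 family (0.947), Wnt targets (0.98), autophagy (0.719), p53 targets (0.649) and stromal markers (0.98), as it did for Wnt targets in fry (0.25) and NF-kB targets without the dimmest 30% of genes (0.961). Leaving out 1 array gave PRKCB values from -0.0505 (without treated replicate 3) to 0.0373 (without treated replicate 2), and cyclic loess gave -0.13. Of 155 called named genes, 138 kept call and direction under every alternative run for single genes, which leaves out the stricter thresholds and all probe sets, and 13 lost the call after cyclic loess. Most of these genes were picked on the same arrays for large changes or small p, which favours keeping the call. Over all 6568 calls, 68.64% to 75.52% were kept in the same direction without 1 untreated array, and 80.45% to 84.21% without 1 treated array. The first component held 72.4% of the variance with the array medians set equal, 68.9% after cyclic loess, 80.4% without the dimmest 30% of genes and 71.4% with the mean of a gene's probe sets. For these shifts the cause was not tested. The robust prior does not enter camera and gave no list values, and lists were not run on all probe sets. With no detection calls, signal over background is not known.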

Other observations

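All lists in this part, and their tests, were chosen after the data were seen. Genes of mitochondrial gene expression and of RNA processing fell beside the list of ribosome assembly and MYC targets. That list shares POLR1A and POLR1B with the polymerase list below, so these lists are not separate. Of 29 mitochondrial ribosomal proteins, 23 fell and 0 rose (24 and 1 adjusted over the list alone), among them MRPS22 at -1.04 ± 0.07 (SE), MRPL13 at -0.99 ± 0.10 and MRPS30 at -0.77 ± 0.07. The median was -0.43 (adjusted p = 7.73e-09; adjusted p = 0.0881 with an estimated correlation). Of 14 genes of mitochondrial DNA maintenance and transcription, 9 fell and 0 rose (10 and 0 adjusted over the list alone), including the transcription factor genes TFB2M at -1.62 ± 0.09 and TFAM at -0.61 ± 0.08 and the helicase gene TWNK at -1.24 ± 0.08. That list had an adjusted p of 3.93e-05 (adjusted p = 0.15 with an estimated correlation). Among 21 subunits of the RNA exosome and RNase P, 15 fell and 1 rose (15 and 2 adjusted over the list alone), with EXOSC5 at -1.70 ± 0.09, RPP40 at -1.48 ± 0.07 and EXOSC7 at -0.79 ± 0.09 (adjusted p = 3.72e-05; adjusted p = 0.15 with an estimated correlation). Of 21 subunits and initiation factors of RNA polymerases I and III, 14 fell and 2 rose (15 and 2 adjusted over the list alone), and of the 16 subunits among them 12 fell and 1 rose, with POLR1G at -0.85 ± 0.07 and POLR3D at -0.74 ± 0.08 (adjusted p = 3.93e-05; adjusted p = 0.0881 with an estimated correlation). After cyclic loess the medians of these 4 lists, in the order given, were -0.28, -0.26, -0.18 and -0.19, and all 4 lists still passed. Without the 3 members of smallest p of each list they had medians of -0.39, -0.37, -0.35 and -0.33 and adjusted p of 3.94e-07, 0.00467, 0.0018 and 0.0018 (0.103, 0.29, 0.29 and 0.117 with an estimated correlation). After cyclic loess as well, the adjusted p without these members was 0.0035, 0.0468, 0.0733 and 0.114, so the exosome and polymerase lists no longer passed.

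In 3 other groups few members passed or members went both ways. Of 9 SLAM family receptors and adaptors, 3 fell and 0 rose, with the same counts adjusted over the list alone: LY9 at -1.58 ± 0.09 (SE), beside SLAMF7 and SLAMF1 (adjusted p = 0.0288; adjusted p = 0.15 with an estimated correlation). That p rests on these 3, of which SLAMF7 and SLAMF1 were known before the list was made; the other 6 had a median of -0.04 (adjusted p = 0.928). Of 25 genes of sphingolipid metabolism, 8 rose and 6 fell (10 and 8 adjusted over the list alone; adjusted p = 0.158). The ganglioside synthase gene ST3GAL5 rose by 1.43 ± 0.08 and the desaturase gene DEGS1 by 1.23 ± 0.11, while UGCG, the first enzyme of glucosylceramide synthesis, changed by -1.43 ± 0.09. Among 18 clock genes, 4 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.158): NR1D2, PER2 at -0.97 ± 0.08, BHLHE40 at -0.72 ± 0.13 and NR1D1 at -0.46 ± 0.10 fell. After cyclic loess the sphingolipid and clock lists each passed in camera with its preset correlation (adjusted p = 0.0126 in both). Without that scaling they did not pass with an estimated correlation either (adjusted p = 0.207 in both). Without their 3 members of smallest p they had adjusted p of 0.385 and 0.967, and 0.0468 and 0.243 after cyclic loess.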
